A study of Mus musculus with 6 samples.

How the data were processed

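RNA from sorted alveolar macrophages of 8-week-old mice was sequenced after polyA selection, per the labels' protocols, in 3 WT and 3 Men1 KO libraries. The alignment tools HISAT and Bowtie2 and the genome build GRCm38.p6 are named in the submitters' processing notes, with no role or order, and the counter and annotation are not given in the sources used here. The authors deposited 1 table with a column per library for each of several units. The deposited expected counts per gene are estimated read counts and are not whole for 8.66% to 9.19% of genes, so they were rounded to whole numbers first. FPKM values (fragments scaled to gene length and library size) and TPM values (transcript shares scaled to a fixed total) were computed by the authors, per the file headers. A normalised count signal was also deposited, which equals the estimated count times 1 constant per library (0.974 to 1.02), and it was not used. A table for a heat map holds log2(FPKM + 1) values of the authors for 6784 genes, as tested on the file. The deposited means per group were not used in tests.

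The expression table lists 15824 genes, and no listed gene has 0 counts in every library. Gene identifiers of 15774 genes matched the RefSeq gene table of build GRCm38.p6, which gave the coordinates. Counts per library totalled 19955242 to 20151990, and the 10 most abundant genes took 12.79% to 13.68% of them. A count of 3 in a library, the floor used here for a count of 0, corresponds to 0.149 to 0.150 CPM. Libraries of a group were compared by a chi-square test of their counts, which found differences beyond counting noise in every pair. Such differences do not show that the libraries came from separate animals, but each library was counted as its own sample.

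The KO and WT groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr filter, design with group only) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 11817 genes and removed 4007. The 41 gene lists were fixed before the data were examined, and 38 had at least 5 tested members. They were tested with camera of limma 3.58.1 (two-sided, preset correlation of 0.01), and beside it with an estimated correlation and with fry, adjusting over the 38 lists. Camera compares the genes of a list with all other genes, while fry asks only whether they move, on balance, in 1 direction. Gene tests were also adjusted over each list alone. CPM values are counts scaled to the TMM-adjusted library sizes. The named genes are Men1, the 10 highest and 10 lowest fold changes among genes that passed, had groups that did not overlap and reached 5 CPM, the 5 most abundant genes changed at least 2-fold in each direction, and up to 4 genes per list by smallest p. Fewer of these are named than the rule allows, and some are not reported here. Other genes are said to be chosen after their values were seen.

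Gene copies that share reads, such as Rpl34 and its pseudogene Rpl34-ps1, are uncertain because the counting method is not stated. The same holds for overlapping and antisense genes, since strand use is not stated. The gene test was checked on simulated counts for the KO against WT comparison, with 11688 genes in that step. It called 42 of 50 genes changed 1.25-fold, all 50 of those changed 1.5-fold, 2-fold and 3-fold, and 8 of 11488 unchanged genes. The simulated biological coefficient of variation was 1.7%, and the 200 changed genes had WT means of at least 50 counts. The simulation therefore does not cover changed genes with fewer counts, a wider spread between animals or changes in most genes. Alternatives listed before the data were examined were other library scaling, other low-count filters, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(TPM + 1) with pseudocounts of 1 and 0.1, other thresholds and other list tests. A correction for GC content and length (97.2% of genes had both), a fit without X and Y genes, an assumed biological coefficient of variation of 0.1 and lists without fibroblast genes were added after the data were seen. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining tests and plots. The list of mitochondrially encoded transcripts had no gene in the table and is not analysed here, the airway epithelial list had fewer than 5 tested members, and the sex-linked list was described per library and not tested.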

Results

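Gene expression was measured by RNA sequencing in alveolar macrophages, the resident phagocytes of the airspaces, sorted by flow cytometry from the lungs of mice aged 8 weeks. The 6 libraries comprised 3 from wild-type mice (WT) and 3 from mice in which Men1 had been knocked out (KO). Men1 encodes menin, a scaffold protein of the MLL histone methyltransferase complexes. The comparison of KO with WT asks which genes depend on Men1 in these macrophages. Total counts per library lay between 19955242 and 20151990, over 15824 listed genes. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. That spread was small, because the chi-square of the counts per gene was 1.39 to 1.61 between libraries of the same group and 62.1 to 65.2 between libraries of different groups.

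Men1 itself was lower in every KO library. Its counts were 639, 594 and 603 in WT libraries 1, 2 and 3, and 150, 149 and 165 in KO libraries 1, 2 and 3. The mean fell from 29.98 ± 1.20 CPM, the read count scaled to library size (SD, n = 3), in WT to 7.88 ± 0.458 CPM (SD, n = 3) in KO, a log2 fold change of -1.93 (SE 0.0684; adjusted p = 7.24e-24, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene lies on chromosome 19 from position 6334979 to 6340894 in GRCm38.p6 (gene ID 17283). The counts are per gene and not per exon, so the deleted part cannot be separated from the rest of the transcript, and KO libraries kept a 3.80-fold lower but measurable signal.

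**Figure D1:**
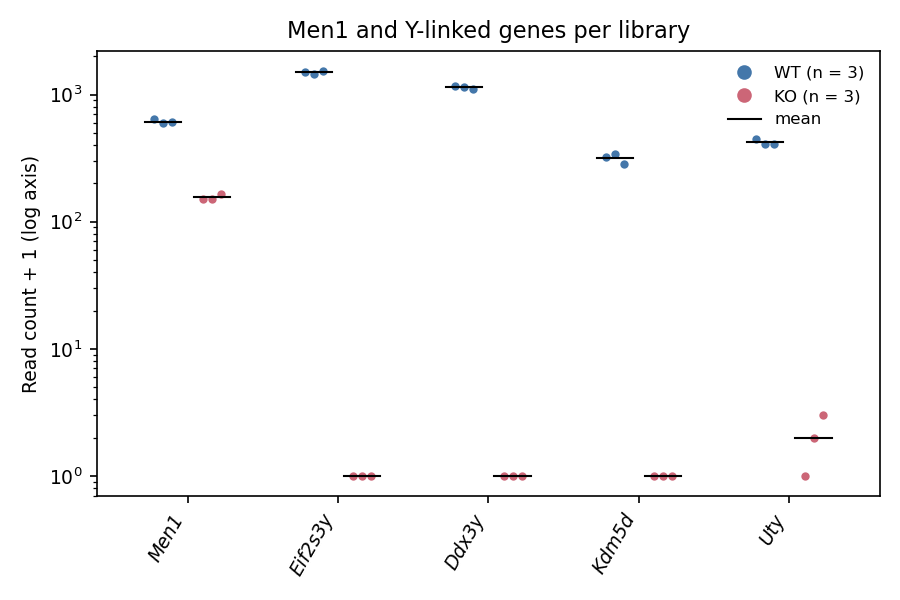
Read counts plus 1 on a log axis for Men1 and 4 Y-linked genes, with 1 point per library (WT blue, KO red, n = 3 each) and the group mean as a line. Men1 lies between 594 and 639 counts in WT and between 149 and 165 in KO, while Eif2s3y, Ddx3y and Kdm5d are at 0 in every KO library.

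KO libraries had lower expression of genes of the G2 and M phases of the cell cycle (45 of 46 lower) and of fibroblast markers (15 of 16 lower), and higher expression of complement and efferocytosis genes (20 of 27 higher) and of phagocytic and scavenger receptor genes (21 of 28 higher). Of 11817 genes tested, 8179 (69.2%) passed an adjusted p threshold of 0.05 in edgeR's quasi-likelihood test, 4060 higher and 4119 lower in KO. Most changes were small, with a median absolute log2 fold change of 0.34 among the genes that passed. On the TPM scale, limma found 2307 genes higher and 5427 lower. A change of at least 2-fold was found for 969 genes, 385 higher and 584 lower. With an assumed biological coefficient of variation of 0.1 in place of the 1.66% estimated from these libraries, 4406 genes passed, and on log2(FPKM + 1) limma gave 340 genes with at least a 2-fold change. The sexes of the animals are not given, and the 4 Y-linked genes described below had at least 283 counts in each WT library and at most 2 in each KO library, so every difference between KO and WT in this report is also a difference between libraries with and nearly without Y-linked transcripts.

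Leaving aside genes at the floor in WT, described below, the acute-phase protein gene Saa3 had the highest fold change of the named genes, from 381 ± 8.71 to 4327 ± 16.3 CPM, which is 11.4-fold (log2 3.51, SE 0.0185; here and below, levels are mean CPM ± SD with n = 3 per group). Cfb, which encodes complement factor B, rose 11.1-fold from 23.98 ± 0.904 to 267 ± 2.35 CPM. The interferon-induced gene Ifi44 rose 10.7-fold from 4.28 ± 0.314 to 45.9 ± 2.21 CPM, and the aspartic protease gene Ctse rose 10.01-fold from 3.02 ± 0.296 to 30.3 ± 0.978 CPM. The chemokine gene Cxcl12 fell from 8.36 ± 1.03 to 0.306 ± 0.0503 CPM and was 26.8-fold lower in KO. Padi4, encoding a protein-citrullinating enzyme, was 13.3-fold lower, the matricellular growth factor gene Ccn2 was 13.03-fold lower, and Serping1, the C1 inhibitor gene, was 11.3-fold lower. Adjusted p-values of these 8 genes in edgeR's quasi-likelihood test ran from 3.6e-50 for Saa3 to 4.25e-19 for Serping1.

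The most abundant genes with at least a 2-fold change included macrophage surface and effector genes. Adgre1, which encodes the F4/80 antigen, rose from 1291 ± 18.4 to 3285 ± 13.7 CPM, and Cybb, a subunit of the phagocyte NADPH oxidase, rose from 1313 ± 19.3 to 2732 ± 43.4 CPM. Apoe, a lipid carrier gene, rose 5.67-fold from 274 ± 4.79 to 1553 ± 85.0 CPM, and the scavenger receptor gene Marco rose 6.60-fold from 172 ± 2.17 to 1137 ± 22.8 CPM. In the other direction, Spp1, which encodes osteopontin, fell from 3757 ± 22.7 to 1527 ± 28.0 CPM, and the beta-catenin gene Ctnnb1 fell from 1914 ± 7.73 to 807 ± 2.85 CPM. Mmp12, the macrophage elastase gene, fell from 1167 ± 18.5 to 413 ± 3.70 CPM, Mfge8, a bridging molecule for apoptotic cells, from 387 ± 2.60 to 193 ± 2.74 CPM, and the cytokine receptor gene Il7r from 340 ± 7.31 to 126 ± 3.23 CPM.

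**Figure D2:**
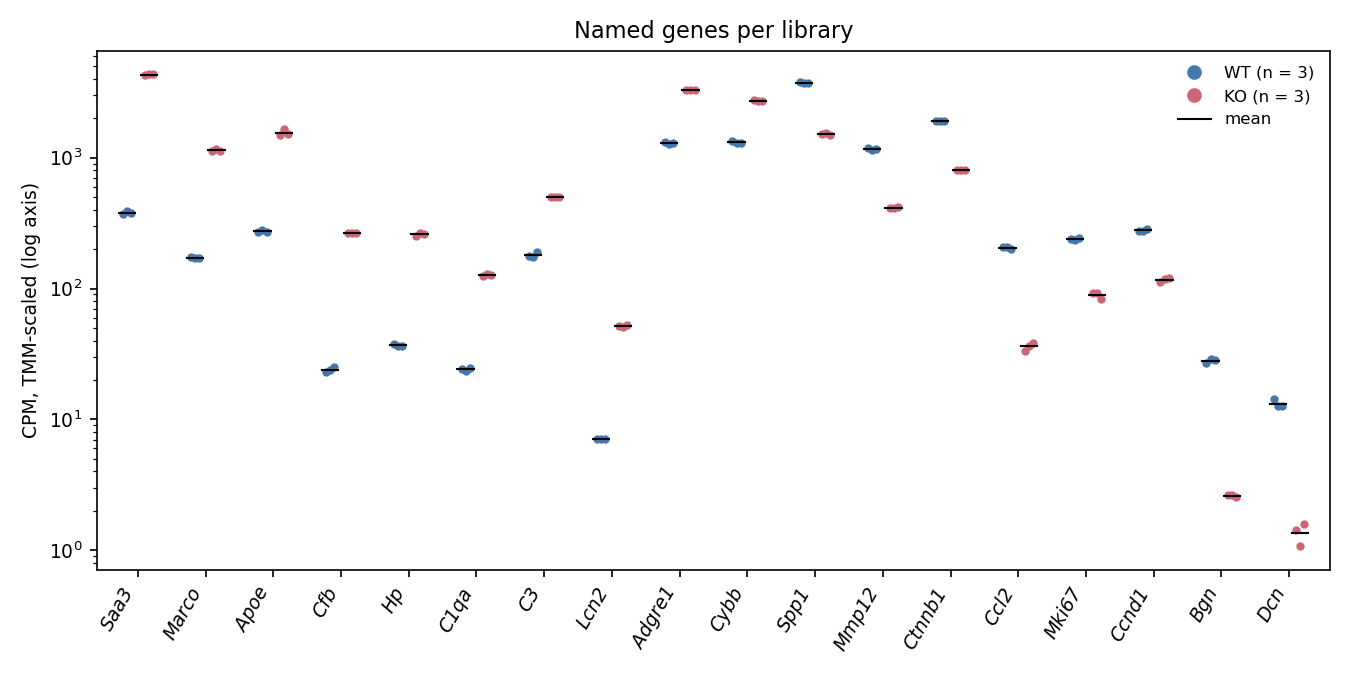
Normalised expression in CPM on a log axis for 18 of the named genes, with 1 point per library (WT blue, KO red, n = 3 each) and the group mean as a line. The points of a group overlap closely for abundant genes, and Saa3 moves from 381 to 4327 CPM while Spp1 moves from 3757 to 1527 CPM.

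Genes of the G2 and M phases of the cell cycle fell almost without exception. Here and below, the numbers of list members that rose or fell are those passing the test over all genes, and the counts adjusted over the list alone differed by at most 1 gene per direction. Of 46 members tested, 45 fell, 33 of them by at least 2-fold, and 1 rose, and the median log2 fold change was -1.26. The proliferation marker Mki67 fell from 239 ± 2.63 to 89.4 ± 5.31 CPM, Top2a, encoding the topoisomerase of dividing cells, from 220 ± 1.68 to 97.7 ± 3.63 CPM, and the cyclin genes Ccna2 and Ccnb1 were 2.69-fold and 2.77-fold lower. The list passed the camera test with an adjusted p of 5.05e-46 and with an adjusted p of 0.00237 when the correlation between genes was estimated, both limma's competitive test. In the list of S phase genes, 23 of 45 were lower and 12 higher, with a median of -0.13. Rrm2, a ribonucleotide reductase subunit, E2f2 and the cyclin gene Ccne2 were 2.15-fold, 2.11-fold and 2.43-fold lower. The S phase call was marginal, with a camera adjusted p of 0.0487, 0.172 with an estimated correlation, and it was lost when WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 2 was left out (adjusted p = 0.0579, 0.0527, 0.0551 and 0.0572) and with a stricter low-count filter (0.0513).

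A list of cell cycle inhibitors and known menin-MLL target genes also shifted down, with 9 of 15 tested members lower and 2 higher (camera adjusted p = 0.0018). With an estimated correlation its adjusted p was 0.154. Its leading members were Ccnd1, which encodes cyclin D1 and fell 2.40-fold from 279 ± 4.71 to 117 ± 3.84 CPM, the cell cycle inhibitor gene Cdkn1a, which was 1.63-fold lower, and the histone demethylase family gene Jmjd1c, which was 1.47-fold lower.

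Receptors for phagocytosis and scavenging rose as a group, with 21 of 28 members higher and 2 lower (camera adjusted p = 3.93e-16, 0.0331 with an estimated correlation). Besides Marco, these included Fcer1g, the signalling chain of Fc receptors, which rose from 330 ± 4.98 to 675 ± 18.2 CPM, the C-type lectin gene Clec4e, which rose 1.90-fold, and the Toll-like receptor gene Tlr1, which rose 2.78-fold. Complement and efferocytosis genes rose in 20 of 27 cases and fell in 6 (camera adjusted p = 6.16e-14, 0.0352 with an estimated correlation). C1qa, encoding a chain of C1q, rose 5.23-fold from 24.1 ± 0.595 to 126 ± 2.29 CPM, C3 rose 2.75-fold and the properdin gene Cfp rose 2.38-fold.

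Markers of interstitial macrophages, which live in the lung tissue instead of the airspace, rose in 15 of 20 cases and fell in 3, with a median of 0.98 (camera adjusted p = 6.16e-14, 0.0448 with an estimated correlation). Fcrls rose 2.44-fold, C1qc 2.22-fold and the scavenger receptor gene Stab1 1.87-fold. Markers of monocytes and recruited macrophages rose in 18 of 29 cases and fell in 6, with a median of 0.34 (camera adjusted p = 2.78e-12, 0.0226 with an estimated correlation). The haptoglobin gene Hp rose 7.06-fold from 36.8 ± 0.441 to 260 ± 5.59 CPM, while Spp1 moved against its list.

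Genes of surfactant and lipid handling rose in 19 of 27 cases and fell in 5, with a median of 0.28 (camera adjusted p = 3.52e-07, 0.0331 with an estimated correlation). After Apoe, the leading members were the phospholipid transfer protein gene Pltp, which rose 3.71-fold, the lysosomal phospholipase gene Pla2g15, which rose 2.14-fold, and the desaturase gene Scd1, which rose 2.25-fold. Inflammatory cytokine and chemokine genes of the NF-kB list rose in 26 of 40 cases and fell in 12, with a median of 0.44 (camera adjusted p = 8.8e-05, 0.0448 with an estimated correlation). Its chemokine genes divided, as the monocyte attractants Ccl2 and Ccl7 fell 5.68-fold and 5.11-fold while Ccl6 rose 2.36-fold. Genes of antigen presentation on MHC class II rose in 11 of 17 cases and fell in 1 (median 0.34, camera adjusted p = 6.8e-05, 0.0448 with an estimated correlation). The class II genes H2-Aa and H2-Ab1 rose 1.56-fold and 1.58-fold, the invariant chain gene Cd74 rose 1.52-fold, and Ctss, encoding cathepsin S, rose from 4592 ± 33.3 to 5825 ± 133 CPM.

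Fibroblast, smooth muscle and mesothelial markers were lower in KO in 15 of 16 cases, with a median log2 fold change of -2.45 (camera adjusted p = 2.33e-07, 0.0331 with an estimated correlation). These genes were expressed at low levels in both groups. Bgn, Dcn, Col6a1 and Col1a2, all extracellular matrix genes, had 28.1 ± 0.939, 13.2 ± 0.999, 9.34 ± 0.538 and 11.8 ± 1.23 CPM in WT, and 2.61 ± 0.0587, 1.36 ± 0.259, 0.985 ± 0.0791 and 1.698 ± 0.211 CPM in KO. Genes of matrix remodelling and growth factors fell in 21 of 32 cases and rose in 9 (median -0.54, camera adjusted p = 2.33e-07). With an estimated correlation the adjusted p was 0.0518. Next to Spp1 and Mmp12, the urokinase gene Plau fell 2.48-fold and Gpnmb, a lysosomal glycoprotein gene among the most abundant transcripts, fell from 22990 ± 209 to 14560 ± 67.1 CPM. The TGF-beta response list fell in 13 of 26 cases and rose in 6 (camera adjusted p = 0.0402, 0.211 with an estimated correlation), and its adjusted p was 0.0551 without KO replicate 1 and 0.0953 without the low-count filter. The receptor gene Tgfbr2 and the target Id1 were 1.95-fold and 2.22-fold lower, whereas the target Tgfbi was higher at 1099 ± 7.71 against 742 ± 4.09 CPM.

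Other lists passed camera with its preset correlation and not with an estimated correlation. MHC class I genes rose in 14 of 20 cases, with H2-K1 1.72-fold and B2m 1.28-fold higher (camera adjusted p = 0.00388, 0.0858 with an estimated correlation). Type I interferon response genes rose in 22 of 38 cases and fell in 9, with Rtp4 1.66-fold higher after Ifi44 (0.012, and 0.0914 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 25 cases and fell in 3, with the regulator gene Srebf2 1.42-fold higher (0.00879, and 0.219 with an estimated correlation). Cytosolic ribosomal protein genes rose in 67 of 76 cases with a median of 0.20, as for Rps14, while Rpl34 fell (1.1e-06, and 0.397 with an estimated correlation). Glycolysis genes rose in 15 of 22 cases, including Gpi1 at 1.32-fold and Slc2a6 at 1.93-fold (0.0081, and 0.212 with an estimated correlation). Oxidative phosphorylation genes rose in 36 of 48 cases, including Cox4i1 at 1.249-fold, while Atp5e was 1.65-fold lower (0.0314, and 0.397 with an estimated correlation). On the TPM scale the medians of glycolysis and oxidative phosphorylation turned to -0.05 and -0.02. The list of ATF4 and unfolded protein response genes fell in 17 of 30 cases, with the cystine transporter gene Slc7a11 1.78-fold lower (0.0487, and 0.179 with an estimated correlation), and its adjusted p was 0.0521 without WT replicate 1, 0.0614 without KO replicate 1 and 0.0513 with a stricter low-count filter. All the p-values in this paragraph are adjusted p-values of the camera test.

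**Figure D3:**
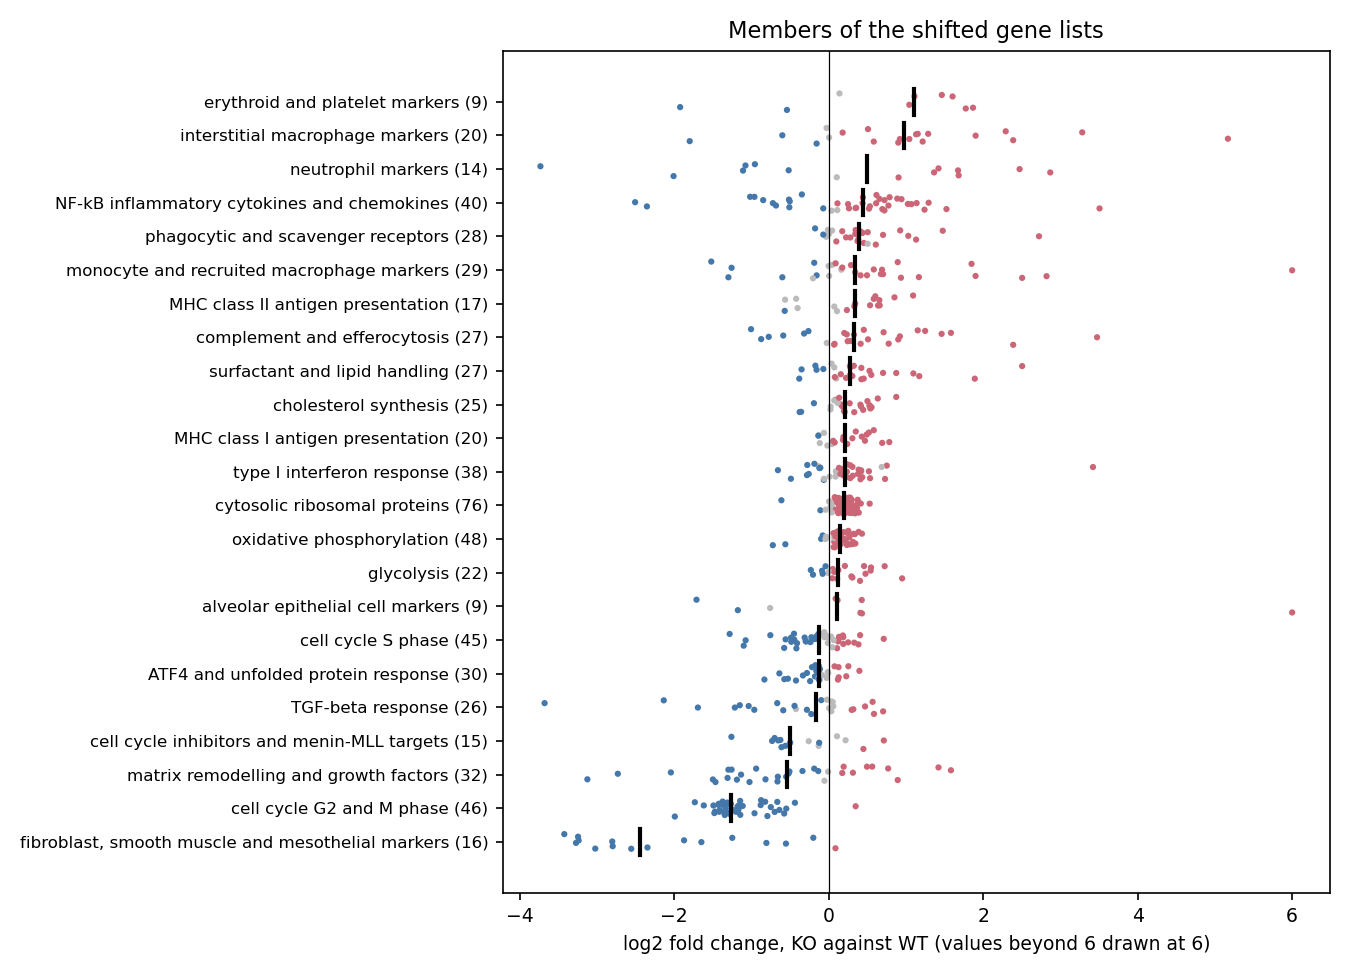
Log2 fold change of KO against WT (x axis) for each tested member of the 23 lists that passed camera, with the number of members in brackets, points coloured by direction where the gene passed the test and grey otherwise, and the list median as a black bar. The fibroblast list has the lowest median at -2.45 and the G2 and M phase list follows at -1.26.

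Among genes with a mean of at least 40 counts in either group, 14 had at most 3 counts in every library of the other group, 4 of them on the Y chromosome. Eif2s3y, Ddx3y and Kdm5d had no counts in KO and were at least 499-fold, 378-fold and 105-fold lower there than in WT, against a floor of 3 counts per library. Uty was 404-fold lower (95% counting interval 138 to 1960). Ifi44l, an interferon-induced gene, had no counts in WT and was at least 61.3-fold higher in KO. Chil1, a chitinase-like gene, was 1070-fold higher in KO (418 to 3930), Vill 377-fold higher (129 to 1830) and the guanylate-binding protein gene Gbp2b 116-fold higher (45 to 427). Intervals and floors cover counting error only, since the reads carry no known molecular identifiers. On the sex chromosomes, 50 of the 969 genes with at least a 2-fold change were located, and 919 genes reached a 2-fold change when X and Y genes were left out of the fit.

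Several marker genes of alveolar macrophages had few counts in all 6 libraries, while most general macrophage genes were abundant. The median level of the 5 listed markers without near-identical copies (Siglecf, Fabp1, Atp6v0d2, Plet1 and Trim29) was 0.43 CPM in WT and 1.34 CPM in KO. Siglecf, the surface lectin used to gate alveolar macrophages, was at 2.06 ± 0.381 CPM in WT and 1.34 ± 0.154 CPM in KO. The general macrophage genes Csf1r, Cd68, Adgre1, Mpeg1, Mertk and Itgam had a median of 1310 CPM in WT and 2250 CPM in KO, with Mertk the lowest at 14.1 ± 0.716 and 42.2 ± 2.04 CPM. Of the 5 markers, Atp6v0d2 was clearly expressed, at 119 ± 3.99 CPM in WT and 60.8 ± 0.928 CPM in KO. Among markers with near-identical copies, Chil3 was at 6.94 ± 0.349 CPM in WT and 13.9 ± 0.676 CPM in KO. Ear1, Ear2 and Ear6 were at 0.0814, 0.0817 and 0.0491 CPM in WT and 0.0681, 0.0679 and 0.0340 CPM in KO. The tested members of the alveolar macrophage identity list, which include genes that other macrophages share, such as Marco and Ctsk, had a median of 95.4 CPM in WT and 67.3 CPM in KO. Of the 34 genes of that list, 29 are in the expression table and 23 were tested. The low-count filter took out members with almost no counts, such as Fabp1 and Plet1, so this median covers expressed members only. The genes named in this paragraph, apart from Adgre1, Atp6v0d2, Chil3, Marco and Ctsk, were chosen after their values were seen. As a group, the alveolar macrophage identity list did not pass camera (adjusted p = 0.688), with 11 of 23 members higher and 10 lower.

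**Figure D4:**
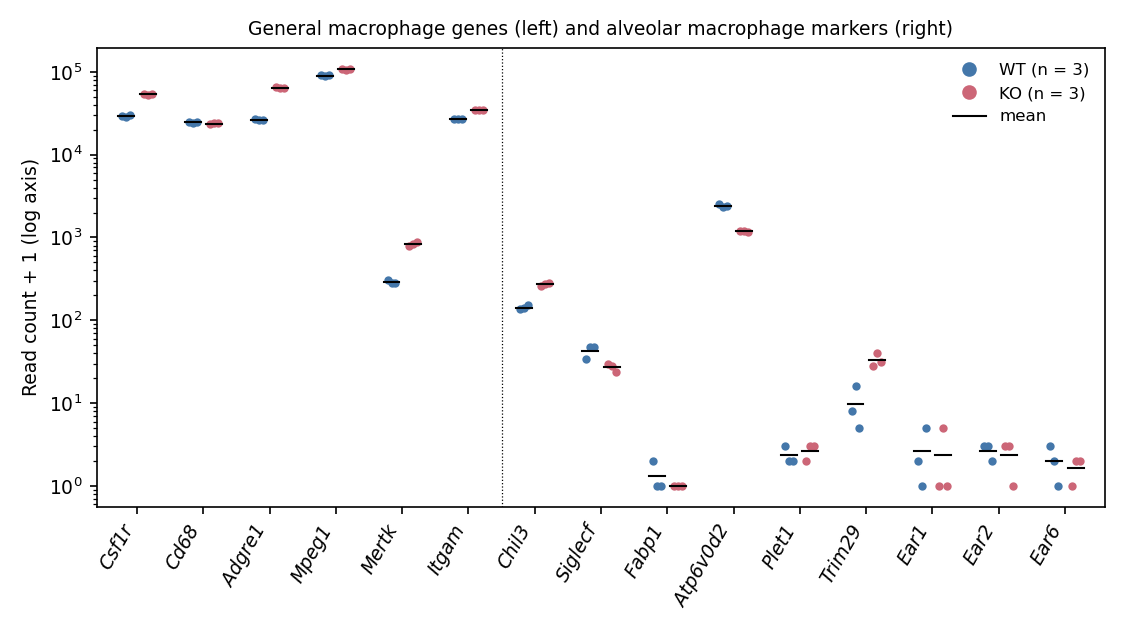
Read counts plus 1 on a log axis for general macrophage genes (left of the dotted line) and alveolar macrophage markers (right), with 1 point per library (WT blue, KO red, n = 3 each) and the group mean as a line. Csf1r has at least 28800 counts in every library while Siglecf has 23 to 47 counts, and Chil3, Atp6v0d2 and Mertk lie between these groups.

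A further file deposited with the series lists genes of a WT against KO heat map, and it was compared with the test results. Of the 6784 genes in the authors' deposited table, 6630 were tested, and all 6630 passed the adjusted p threshold in edgeR's quasi-likelihood test, which is 97.7% of the table. Within these, 3343 were higher and 3287 lower in KO. The table's values equalled log2(FPKM + 1) of the expression table, and how its genes were chosen is not given in the sources used here. DESeq2 called 6917 genes, and 6783 of these were in the authors' table. Its genes may therefore have been chosen as changed in these same libraries, and the overlap with edgeR is no independent support.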

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

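The counts of changed genes, of genes with a 2-fold change and of lists stayed within 1.5 times of the main count in the settings not named here, and Men1 was lower and past the threshold in all settings run. The alternatives named as added in the methods were chosen after seeing the data. The number of genes changed at least 2-fold, 969 in the main analysis, was 340 with limma on log2(FPKM + 1) with or without the low-value filter, 560 on log2(FPKM + 0.1), 410 on log2(TPM + 1) and 412 on that scale without the filter, and the cause was not tested. Gene lists past their threshold were 9 with an estimated correlation and 37 with fry, which does not compare lists with other genes, against 23 with camera. Without the low-count filter 21 lists passed, with TGF-beta response, neutrophil and alveolar epithelial lists lost (adjusted p = 0.0953, 0.153 and 0.429) and dendritic cell markers gained (0.0357), and with the stricter filter 21 passed, with S phase and ATF4 lost (both 0.0513). Of the deposited heat map genes, 100% after rounding (6783 of 6784) were called by DESeq2 and 13.8% by edgeR with a 2-fold bound. With an assumed biological coefficient of variation of 0.1, 4406 genes passed instead of 8179, so that count rests on the small spread between libraries of a group. Leaving out each library in turn gave 7755 to 7935 genes, 1008 to 1057 genes with a 2-fold change, a Men1 log2 fold change of -1.97 to -1.89, and 20 to 23 lists. TPM scaling moved the median of all tested genes to -0.12 on log2(TPM + 1), and 2307 genes were then higher and 5427 lower, against 4060 and 4119. Among 131 genes followed, only Cd68 changed sign, from a positive value that rounds to 0.00 and did not pass the test to negative values, which round to 0.00 with upper-quartile scaling and without KO replicate 2 or 3, and were -0.06 on the FPKM scales, -0.14 on the TPM scales and -0.10 after GC and length correction (its range over the fits without 1 library was 0.00 to 0.02). The replicate numbers were not treated as pairs, as same-numbered WT and KO libraries had correlations of deviations of 0.099, 0.035 and 0.056, each the highest for its library, which is a hint from the data and not the design. With the replicate block 8321 genes passed, 969 with a 2-fold change, Men1 stayed at -1.93 and 21 lists passed, with calls of TGF-beta response (0.0511), alveolar epithelial (0.117) and neutrophil lists (0.169) not made and dendritic cell markers (0.0403) added.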

Other observations

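The tests on alveolar markers, fibroblast genes, exchanged libraries, strain and the gene counts of other splits were chosen after the result was seen, while the tests on X-linked genes, the neighbourhood of Men1 and the list counts of other splits were written before. Further lists fixed in advance also held individual changes. Neutrophil markers divided, with Lcn2, Csf3r and Mmp9 7.30-fold, 3.21-fold and 2.68-fold higher in KO and Mmp8 1.43-fold lower, 7 higher and 6 lower of 14 (camera adjusted p = 0.0402, 0.172 with an estimated correlation, 0.0579 without WT replicate 1 and 0.153 without the low-count filter). Erythroid and platelet markers rose in 6 of 9 cases, among them the platelet genes Ppbp, Itga2b and Pf4 at 3.04-fold, 3.42-fold and 2.06-fold, and fell in 2 (camera adjusted p = 0.00395, 0.0914 with an estimated correlation). Alveolar epithelial markers rose in 6 of 9 cases, including the lipid transporter gene Abca3 at 1.35-fold, with Pdpn 3.28-fold lower (camera adjusted p = 0.012, 0.212 with an estimated correlation and 0.429 without the low-count filter), and on log2(TPM + 1) without a filter their median was -0.03 instead of 0.11.

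The remaining lists did not pass camera in the main analysis. Lysosome genes went both ways (27 of 50 higher, 21 lower, adjusted p = 0.713), with the galactosidase gene Glb1 2.33-fold and Ctsl 1.44-fold higher and Ctsk 1.90-fold lower. Alternative activation genes were 7 higher and 6 lower of 17 (0.395), and Mrc1 and Chil3 were 1.37-fold and 2.01-fold higher. Fatty acid oxidation genes were 13 higher and 8 lower of 26 (0.688) and fatty acid synthesis genes 12 higher and 6 lower of 20 (0.147), with Acaa1a and Fads1 both 1.38-fold higher. Members of a list of menin-MLL complex subunits and other chromatin regulators were 6 higher and 13 lower of 26 (0.342). Among those other regulators, the histone methyltransferase genes Dot1l and Ezh2 were 1.93-fold and 1.52-fold lower. PI3K, AKT, mTOR and FOXO genes were 15 higher and 11 lower of 33 (0.286), where Igf1 was 1.704-fold higher and Pik3cb 1.96-fold lower. Genes of the p53 list were 9 higher and 16 lower of 31 (0.106), with Sesn1 2.86-fold higher and Mdm2 2.23-fold lower, and antioxidant genes 11 higher and 16 lower of 33 (0.654), with Prdx5 2.79-fold higher and Gstm1 1.67-fold lower. Immediate early and stress genes were 11 higher and 17 lower of 33 (0.147), with Myc 1.86-fold lower. Dendritic cell markers were 12 higher and 3 lower of 18 (0.101, and 0.0357 without the low-count filter), with Cst3 1.67-fold higher and Cd24a 2.09-fold lower. Lymphoid markers of T and NK cells were 4 higher and 4 lower of 10 (0.108), with Cd28 2.22-fold lower, and B cell markers 4 higher of 5 (0.324), with Cd22 1.251-fold higher. Endothelial markers were 4 higher and 5 lower of 12 (0.462), with Kdr 1.45-fold lower, and eosinophil, basophil and mast cell markers 1 higher and 2 lower of 5 (0.946). Values in brackets are camera adjusted p-values. The camera direction was down for lysosome genes although their median was 0.07, and up for fatty acid oxidation although their mean was -0.14 beside a median of 0.10. It was down for T and NK cell markers with a median of 0.00 and a mean of 0.29.

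Of the genes at the floor in only 1 group, the 4 on the Y chromosome may reflect animals of different sex. The test on X-linked genes does not address the 10 autosomal ones. The median log2 fold change of 5 genes that escape X inactivation (Kdm5c, Kdm6a, Eif2s3x, Ddx3x and Pbdc1) was 0.45. That is above the 95th percentile of 0.26 for random sets of X-linked genes. Female KO and male WT animals would give such a rise, and it argues against loss of the Y chromosome alone. However, only Kdm5c, Kdm6a and Eif2s3x rose past the threshold. Ddx3x was lower in KO, and Pbdc1 did not pass (log2 fold change 0.061, adjusted p = 0.192, edgeR's quasi-likelihood test). Xist, the transcript of the inactive X chromosome, is not among the listed genes, so this direct marker of a second X could not be checked. Its absence may mean no counts in any library, which would go against female KO animals, or a gene left out of the listing. No library (0 of 6) had Men1 and Y-linked counts nearer to the other group, so an exchanged library is argued against. A difference in strain stays open, since 2 pairs of the 10 autosomal floor genes lay within 10 Mb of each other, with a permutation p of 0.0692. Genes within 10 Mb of Men1 were not found to change 2-fold more often than others (odds ratio 0.747, 95% interval 0.389 to 1.31, Fisher's exact test, two-sided). This argues against 2-fold changes being much more common near Men1. The test counted only such changes, so it cannot decide on carried-along DNA or on smaller local effects.

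Rpl34-ps1, a pseudogene copy of Rpl34, had 97.8 CPM in KO against 0.0326 CPM in WT, while Rpl34 went from 177 ± 2.84 to 116 ± 2.41 CPM. Their sum was 177 ± 2.82 CPM in WT and 214 ± 1.87 CPM in KO, a log2 ratio of 0.27. Other genes with floor values, chosen after their values were seen, were Klrb1c, higher in KO at 39-fold (counting interval 14.9 to 145), and Acaa1b, Spry4 and Lama4, lower in KO by 61.1-fold (16.6 to 510), 29.1-fold (11.1 to 109) and 21.3-fold (9.54 to 59.1), along with the predicted gene Gm45988, at least 23.8-fold lower.

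Siglecf, Fabp1, Plet1 and Trim29 had few counts in every library while Atp6v0d2 and Chil3 were expressed, and 3 explanations were weighed for the low markers. Dropped reads of near-identical gene copies are argued against, because the 5 listed markers without such copies had a median of 0.43 CPM in WT. This median leaves out 4 of the 9 markers chosen for the test (Car4, Cidec, Krt79 and Krt19). They are not among the listed genes, and whether genes were left out of the listing is not known. Dilution by non-macrophage cells is argued against, because the highest median among 9 lists of other cell types was 3.72 CPM. Macrophages outside the alveolar state (monocyte-derived, recruited or cultured) may be the source, as the lowest library median of 6 general macrophage genes was 1300 CPM, but these levels were known when the test was written and Atp6v0d2 was expressed, so this remains a hypothesis. The sort was for alveolar macrophages and its gate is not given in the labels, and a KO effect cannot account for low markers in WT.

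Fibroblast genes were higher in WT, and a small share of stromal cells in the WT libraries may be the source. All 5 abundant fibroblast transcripts tested (Col1a1, Col1a2, Col3a1, Dcn and Sparc) were at least 2-fold higher in WT, at 4.33 to 13.2 CPM there, which is what a small share of such cells would give. Lower output of matrix genes by KO macrophages could not be told apart from it, since 8 matrix genes of macrophages had a median of -0.26 and went both ways, with Mmp14, Timp2 and Tgfbi higher and Fn1 and Lgals3 lower. Of the 24 fibroblast genes in the table, 0 are also in another list and 3 reached 5 CPM in KO, and a sort for macrophages would remove most fibroblasts.

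With 3 libraries against 3 there are only 10 splits, too few to give a share under 0.05. The real split gave 8179 genes, 969 genes with a 2-fold change and 23 lists, and the highest of the other splits gave 0, 0 and 11, with 1 split in each case as large as the real one, the real one itself.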
